A study of Mus musculus with 11 samples.

How the data were processed

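The material was laser capture microdissected tissue of wild-type CD-1 mouse kidney and ureter at E15.5, per the labels. Fetal kidneys from time-mated mice were frozen, sectioned and stained before capture, per the labels' protocols. The stain and the landmarks that defined each region are not given in the sources used here. Each of the 11 samples was a pool of approximately 50 sections from 5 kidneys, and total RNA was amplified in 2 rounds and labelled with biotin, per the labels' protocols. The deposited values are linear intensity signals of 45101 Affymetrix probe sets, made with GCOS (Affymetrix GeneChip Operating Software, version not stated), per the submitters' processing notes. Every deposited array had the same mean of 1500 over probe sets without the lowest and highest 2%, so the authors' scaling was kept. The values used here carry no detection calls. The compartment of each sample was read from its label, and replicate numbers were given in accession order and pair nothing. Label batch was taken from a date-like part of the titles or source names whose meaning is not stated.

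The values were taken to log2(signal + 55), 55 being the rounded 20th percentile of the table, which makes folds of dim genes smaller than on the raw scale. A probe set was kept if it lay above its array's own median in at least 2 arrays. Of the 45101 probe sets, 64 were Affymetrix controls, 34958 had 1 gene symbol in the annotation used, 932 had several and 9211 are unnamed here. Symbols were checked by Entrez identifier against a RefSeq table of the GRCm38.p6 build for 34754 probe sets, and 0 symbols changed. The filter kept 29565 probe sets, 24427 of them with 1 symbol. A gene with several probe sets was read from the one with the highest mean, leaving 13614 genes.

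A single limma fit (limma 3.58.1, R 4.3.3) gave each compartment a mean and shared 1 estimate of spread over all 11 arrays, with 7 residual degrees of freedom and 6.38 prior degrees of freedom. Each compartment was set against the equally weighted mean of the other 3, and the 6 pairs were compared from the same fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison and an absolute log2 fold change of at least 1. The 28 gene lists hold textbook markers of kidney and ureter compartments, of cell types that dissection can carry over, and of pathways. They were tested with limma's camera at a preset correlation of 0.01, adjusted over 112 tests, and again with an estimated correlation. Named genes followed a rule. For each compartment it took the 12 called genes with the highest and the 6 with the lowest log2 fold change whose arrays did not overlap with those of the other compartments, and up to 4 members of each list with the largest moderated t. For urothelium against collecting duct, urothelium against muscle and collecting duct against proximal tubule it took 6 genes each way, and it skipped symbols made from clone names. Single members that went against their list (Aqp1, Gata2 and Tbx2 in muscle) are named by their count and were chosen after their values were seen. The lists, the tests, the rule and all alternatives but 2 were fixed before the data were examined.

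The alternatives were quantile normalization, pseudocounts of 12 and 190 (the 5th and 40th percentiles), no filter, a filter at the 75th percentile, the mean of a gene's probe sets, no probe sets of the x, s and a types, eBayes with trend and robust options, label batch as a fixed or a random block, and each array left out in turn. The 2 alternatives added later left out the 2 arrays of label batch 2 and the genes on chromosomes X and Y. The procedure was tested on simulated data with 100 genes changed by a log2 of 1.5 and 100 by 3 among 13614. It recovered 23%, 37%, 44% and 36% of the smaller and 82%, 92%, 85% and 94% of the larger changes in collecting duct, proximal tubule, muscle and urothelium, with 0 in the wrong direction and 3, 5, 1 and 5 false calls. The simulated values were drawn independently for each gene and array, without label batches or differences in RNA quality. These rates therefore need not hold for the real arrays. Plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.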

Results

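Gene expression was measured in 4 compartments of the wild-type CD-1 mouse kidney and ureter at E15.5 (Theiler stage 23), each cut from frozen sections by laser capture microdissection. CD-1 is an outbred stock of mice. The 11 one-colour arrays comprised 2 of cortical collecting duct (CCD in the plots), 3 of early proximal tubule (EPT), 3 of ureteral smooth muscle (USM) and 3 of urothelium (URO), the epithelium that lines the ureter. Each sample was a pool of approximately 50 sections from 5 kidneys, and its RNA went through 2 rounds of amplification. The stated purpose was to define the expression profile of each element of the developing kidney, so every compartment was set against the mean of the other 3 and against each of them. Nothing states whether pools shared kidneys or fetuses. The p-values therefore measure the spread between these pools, which may be partly technical and may be too small where pools share animals, and the number of arrays limits the precision.

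For 10 of the 11 arrays the most similar array was of the same compartment, and for collecting duct replicate 2 it was urothelium replicate 3 (r = 0.909, against 0.905 with collecting duct replicate 1). Over the 13614 genes tested, Pearson correlations across genes, which are not independent replicates, ran from 0.884 to 0.933 within a compartment and from 0.714 to 0.909 between compartments. Cortical collecting duct and urothelium were closest (median 0.872), and proximal tubule and ureteral smooth muscle farthest apart (median 0.730). A date-like part of the sample titles or source names splits the arrays into 4 label batches, and urothelium shares no batch with collecting duct or proximal tubule. Pairs of arrays from different compartments had a median correlation of 0.826 within a batch and 0.800 across batches. These 2 sets hold different mixes of compartments, so the medians do not measure an effect of batch alone. The median signal per array was 247 to 401 at a common 2% trimmed mean of 1500. The 3' to 5' signal ratio of the Gapdh control was 16.7, 55.3 and 29.7 in urothelium replicates 1, 2 and 3 and 6.79 to 25.9 in the other 8 arrays. The same ratio of the actin control was 6.66, 5.43 and 5.15 in urothelium replicates 1, 2 and 3. It ran from 5.07 to 13.5 over the 11 arrays and was highest in proximal tubule replicate 2 and collecting duct replicate 2 (13.5 and 13.4). These 2 controls therefore do not rank urothelium alike. The actin 3' control signal was 7167 to 10236 in the 3 arrays of label batch 3 (collecting duct replicate 2 and proximal tubule replicates 2 and 3) and 24831 to 75054 in the rest. Xist, the transcript of the inactive X chromosome, was at 16.09 to 17.33 on the log2 scale in 6 arrays and at 7.83 to 9.56 in 5, with both sides present in collecting duct, smooth muscle and urothelium.

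**Figure D1:**
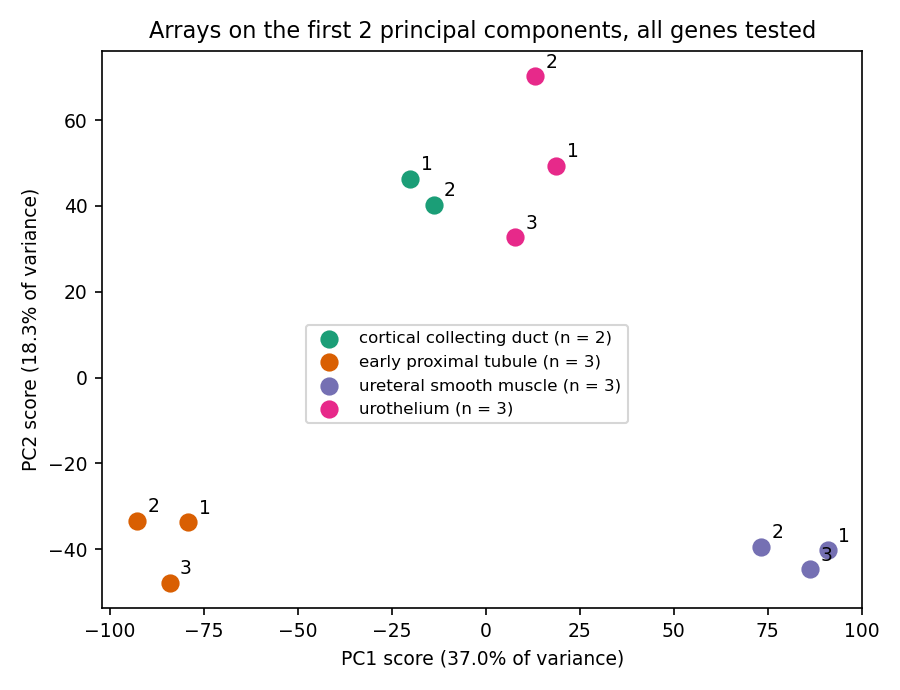
Scores of the 11 arrays on the first 2 principal components of log2 signal over the genes tested (PC1 37.0% and PC2 18.3% of the variance, arbitrary score units), with replicate numbers beside the points and colours for the compartments. Proximal tubule and smooth muscle arrays lie at opposite ends of PC1 (-92.8 to -79.2 and 73.2 to 91.0), and collecting duct and urothelium arrays lie together at the upper end of PC2 (32.8 to 70.2).

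Cortical collecting duct was set apart by Aldh1a3, a retinaldehyde dehydrogenase that makes retinoic acid, which was higher than the mean of the other compartments by a log2 fold change of 6.13 ± 0.57 (SE, n = 2 against 9 arrays). Calb1, the calcium-binding protein calbindin, was higher by 5.79 ± 1.29, with log2 signals of 14.81 and 15.22 in collecting duct and 10.44, 7.13 and 14.35 in urothelium replicates 1 to 3. The hedgehog ligand Shh was higher by 5.27 ± 0.80. The epithelial transcription factors Elf5 and Ehf were higher by 5.55 ± 0.65 and 4.30 ± 0.54, the tight junction protein Cldn8 by 4.67 ± 0.62, and Fxyd4, a regulator of the sodium pump, by 4.37 ± 0.45. Among the genes lower in this compartment, Tubb6, a tubulin, differed by -3.14 ± 0.43, the growth factor Gas6 by -2.95 ± 0.47 and the transglutaminase Tgm2 by -2.85 ± 0.37. The other leading genes were Rgn 5.62, Tenm1 4.93, Mal2 4.72, Muc1 4.41 and Sgpp2 4.29 on the higher side and Abhd14a -2.58, Ccdc107 -2.55 and Pde5a -2.55 on the lower side, with adjusted p from 0.000813 to 0.0351 over all 18 by limma.

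The collecting duct principal cell list had 7 of 13 measured members higher, 0 lower and 6 not called. Principal cell genes gave 12 higher and 0 lower adjusted over the list alone. The list's camera adjusted p was 5.87e-19, and 0.023 with an estimated correlation. Its higher members included Scnn1g 3.73, a subunit of the epithelial sodium channel, and the transcription factor Tfcp2l1 3.31. The ureteric bud and duct list had 5 of 15 measured members higher, 0 lower and 10 not called. Ureteric bud genes gave 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.32e-10), with Wnt9b 4.13, Gata3 3.72 and the GDNF co-receptor Gfra1 3.57. General epithelial genes had 8 of 22 measured members higher, 0 lower and 14 not called. General epithelial genes gave 18 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.02e-19), among them Mal2 4.72, Esrp1 3.0, Cdh16 3.0 and Epcam 2.96. Of the intercalated cell genes the ammonia transporter Rhcg 2.88 was called, with 1 of 8 measured members higher, 0 lower and 7 not called. Intercalated cell genes gave 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00124, and adjusted p = 0.0523 with an estimated correlation). The retinoic acid pathway list had 2 of 13 measured members higher, 0 lower and 11 not called. Retinoic acid genes gave 4 higher and 0 lower adjusted over the list alone, the called members being Aldh1a3 and the retinoic acid hydroxylase Cyp26b1 1.71 (camera adjusted p = 0.00699, and adjusted p = 0.12 with an estimated correlation).

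On the lower side, smooth muscle contractile genes had 0 of 26 measured members higher, 9 lower and 17 not called. Contractile genes gave 0 higher and 17 lower adjusted over the list alone (camera adjusted p = 4.56e-14), among them Myl9 -3.65, Actc1 -3.64 and Acta2 -3.11. The ureteral mesenchyme and hedgehog target list had 0 of 15 measured members higher, 2 lower and 13 not called. Ureteral mesenchyme genes gave 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0212, and adjusted p = 0.353 with an estimated correlation), with Bmp4 -2.43 and Tbx18 -3.17. Extracellular matrix genes had 0 of 27 measured members higher, 1 lower and 26 not called. Extracellular matrix genes gave 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00138, and adjusted p = 0.48 with an estimated correlation), the called member being Dcn -2.34. Proximal tubule transporters had 0 of 31 measured members higher, 3 lower and 28 not called. These transporters gave 0 higher and 5 lower adjusted over the list alone (camera adjusted p = 2.45e-05, and adjusted p = 0.128 with an estimated correlation), with the water channel Aqp1 -2.87 and the anion transporter Slc22a6 -2.67. Proximal tubule metabolism genes had 0 of 30 measured members higher, 0 lower and 30 not called. Metabolism genes gave 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 1.87e-05, and adjusted p = 0.115 with an estimated correlation). Cell cycle genes had 0 of 23 measured members higher, 0 lower and 23 not called. Cell cycle genes gave 0 higher and 0 lower adjusted over the list alone, with a list median of -0.72 (camera adjusted p = 1.47e-06, and adjusted p = 0.123 with an estimated correlation). Oxidative phosphorylation genes had 0 of 33 measured members higher, 0 lower and 33 not called. Oxidative phosphorylation genes gave 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0302, and adjusted p = 0.48 with an estimated correlation), and with label batch as a block that list's direction turned (oxidative phosphorylation camera adjusted p = 0.999, and 0.00938 to 0.999 over the alternatives).

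The other 16 lists were not called in this comparison (camera adjusted p from 0.056 to 0.939), among them the macrophage and leukocyte list, in which Ptprc alone was called (4.2 ± 1.00, limma adjusted p = 0.0493). Leukocyte genes gave 2 higher and 0 lower adjusted over the list alone. In all, limma called 278 of 13614 genes, 193 higher and 85 lower, and 163 of them did not overlap between the 2 collecting duct arrays and the other 9 (5.44% of genes tested did so, against 3.64% by chance). With label batch as a block 3 genes were called (3 higher), while the median log2 size of the 278 genes went from 2.43 to 2.38 and the median SE of all genes from 0.448 to 0.581, and of the 49 called genes that the rule named, 49 lost the call with the block, 3 to 45 without single arrays and 0 to 13 under the other alternatives. Without replicate 1 of the collecting duct 10 genes were called and without replicate 2, 31.

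Early proximal tubule was marked by enzymes and carriers of the mature tubule. Acsm2, a medium-chain acyl-CoA synthetase, was higher than the mean of the other compartments by a log2 fold change of 7.25 ± 0.83 (SE, n = 3 against 8), the glucuronosyltransferase Ugt2b5 by 7.20 ± 0.49 and the fatty acid carrier Slc27a2 by 6.97 ± 0.91. Hdc, the enzyme that makes histamine, was higher by 6.76 ± 0.76, and the cystine and amino acid transporter subunit Slc7a9 by 6.56 ± 0.56. The forkhead transcription factor Foxa1 was lower by the widest margin of the named genes (-7.08 ± 0.39), with mean log2 signals of 6.06 ± 0.02 in proximal tubule (SD, n = 3), 13.24 ± 0.24 in collecting duct (n = 2), 10.92 ± 0.72 in smooth muscle (n = 3) and 15.25 ± 0.80 in urothelium (n = 3). The remaining leading genes were Mep1b 6.53, Cyp2d26 6.52, the glucose transporter Slc2a2 6.49, the organic cation exporter Slc47a1 6.33, Slc17a1 6.29, Amn 6.29 and Slc22a22 6.13 on the higher side, and Car3 -5.31, Cav2 -4.62, Ptger4 -4.49, Sh3bgrl -4.13 and Rgs2 -3.98 on the lower side, with limma adjusted p from 5.97e-07 to 0.00036.

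Proximal tubule transporters had 28 of 31 measured members higher, 0 lower and 3 not called. These transporters gave 28 higher and 0 lower adjusted over the list alone, with a list median of 3.87. Their camera adjusted p was 6.15e-26, and 0.023 with an estimated correlation. Examples were Slc13a1 5.99, a sulfate transporter, Slc6a13 5.17 and Slc3a1 4.74, the partner of Slc7a9. Brush border and endocytosis genes had 17 of 19 measured members higher, 0 lower and 2 not called. Brush border genes gave 19 higher and 0 lower adjusted over the list alone (camera adjusted p = 9.25e-18), among them the vitamin B12 receptor Cubn 5.05, the protease Mep1a 5.39, Cdhr2 5.18 and Pdzk1 4.68. The proximal tubule metabolism list had 23 of 30 measured members higher, 0 lower and 7 not called. Metabolism genes gave 24 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.68e-20), with Spp2 5.71, Cyp2j5 5.14, Gsta2 4.80 and the D-amino acid oxidase Dao 4.17. The loop of Henle and distal tubule list had 4 of 12 measured members higher, 0 lower and 8 not called. Loop of Henle genes gave 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00699, and adjusted p = 0.169 with an estimated correlation). The members called there were Cldn10 3.26, a claudin, and the transcription factors Irx3 2.47, Pou3f3 1.67 and Emx1 1.27. The fatty acid oxidation and peroxisome list was not called (camera adjusted p = 0.105) and had 4 of 24 measured members higher, 1 lower and 19 not called. Fatty acid oxidation genes gave 4 higher and 1 lower adjusted over the list alone, with the peroxisomal thiolase Acaa1b 4.68 higher and the mitochondrial thiolase Acaa2 -2.44 lower.

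Several lists of the other compartments were lower. Not called were the intercalated cell list, with 2 of 8 measured members higher and 0 lower (camera adjusted p = 0.538), the desmosome list, with 2 of 17 higher and 3 lower (camera adjusted p = 0.55), and the general epithelial list, with 4 of 22 higher and 6 lower (camera adjusted p = 0.362). Smooth muscle contractile genes had 0 of 26 measured members higher, 19 lower and 7 not called. Contractile genes gave 0 higher and 21 lower adjusted over the list alone (camera adjusted p = 4.23e-14), with Tagln -3.25 and Actc1 -3.70. Ureteral mesenchyme and hedgehog targets had 0 of 15 measured members higher, 9 lower and 6 not called. Ureteral mesenchyme genes gave 0 higher and 10 lower adjusted over the list alone (camera adjusted p = 1.47e-06, and adjusted p = 0.0867 with an estimated correlation), with Tbx18 -4.27 and Tbx3 -3.72. Extracellular matrix genes had 0 of 27 measured members higher, 11 lower and 16 not called. Extracellular matrix genes gave 0 higher and 11 lower adjusted over the list alone (camera adjusted p = 1.74e-07, and adjusted p = 0.297 with an estimated correlation), with Lum -4.12 and Postn -2.85. Urothelial differentiation genes had 1 of 21 measured members higher, 12 lower and 8 not called. Urothelial genes gave 1 higher and 14 lower adjusted over the list alone (camera adjusted p = 7.18e-08, and adjusted p = 0.121 with an estimated correlation). Foxa1, Krt19 -2.87 and Upk3a -2.79 were among those lower, and the FGF receptor Fgfr3 2.92 went the other way. The principal cell list had 1 of 13 measured members higher, 5 lower and 7 not called. Principal cell genes gave 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.000882, and adjusted p = 0.128 with an estimated correlation), with Scnn1g -3.37 lower and Tfcp2l1 1.86 higher. The ureteric bud and duct list had 2 of 15 measured members higher, 4 lower and 9 not called. Ureteric bud genes gave 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0453, and adjusted p = 0.375 with an estimated correlation), with Gata2 -2.86 and Gata3 -3.48 lower and Pax8 2.09 higher.

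BMP target genes had 0 of 10 measured members higher, 6 lower and 4 not called. BMP targets gave 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.000343, and adjusted p = 0.0811 with an estimated correlation), the inhibitors of DNA binding Id4 -2.77, Id3 -1.67, Id2 -1.61 and Id1 -1.24 all being called. Immediate early and stress genes had 0 of 14 measured members higher, 3 lower and 11 not called. Immediate early genes gave 0 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.00778, and adjusted p = 0.0811 with an estimated correlation), among them the heat shock gene Hspa1b -2.36. The renal interstitium list had 1 of 13 measured members higher, 4 lower and 8 not called. Interstitial genes gave 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.00884, and adjusted p = 0.451 with an estimated correlation), with Pdgfra -2.51 and Zeb2 -2.03 lower and Ntn1 1.13 higher. The other 11 lists were not called (camera adjusted p from 0.0707 to 0.996). Of 13614 genes, limma called 2169, 1297 higher and 872 lower, and 1351 of them did not overlap between compartments (12.5% of genes tested, against 1.21% by chance). With label batch as a block 406 were called (273 higher, 133 lower), 396 of them also called without it. The median log2 size of the 2169 genes went from 1.79 to 1.74 with the block, all keeping their sign on the arrays that chose them, and the median SE of all genes from 0.390 to 0.581. Over the alternatives, of the 92 called genes that the rule named, 43 lost the call with the block, 2 to 17 without single arrays and 0 to 6 under the other alternatives, the leading genes Slc2a2 and Amn among those lost with the block. Without proximal tubule replicate 2 the count was 1232 and without replicate 3 it was 1402.

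**Figure D2:**
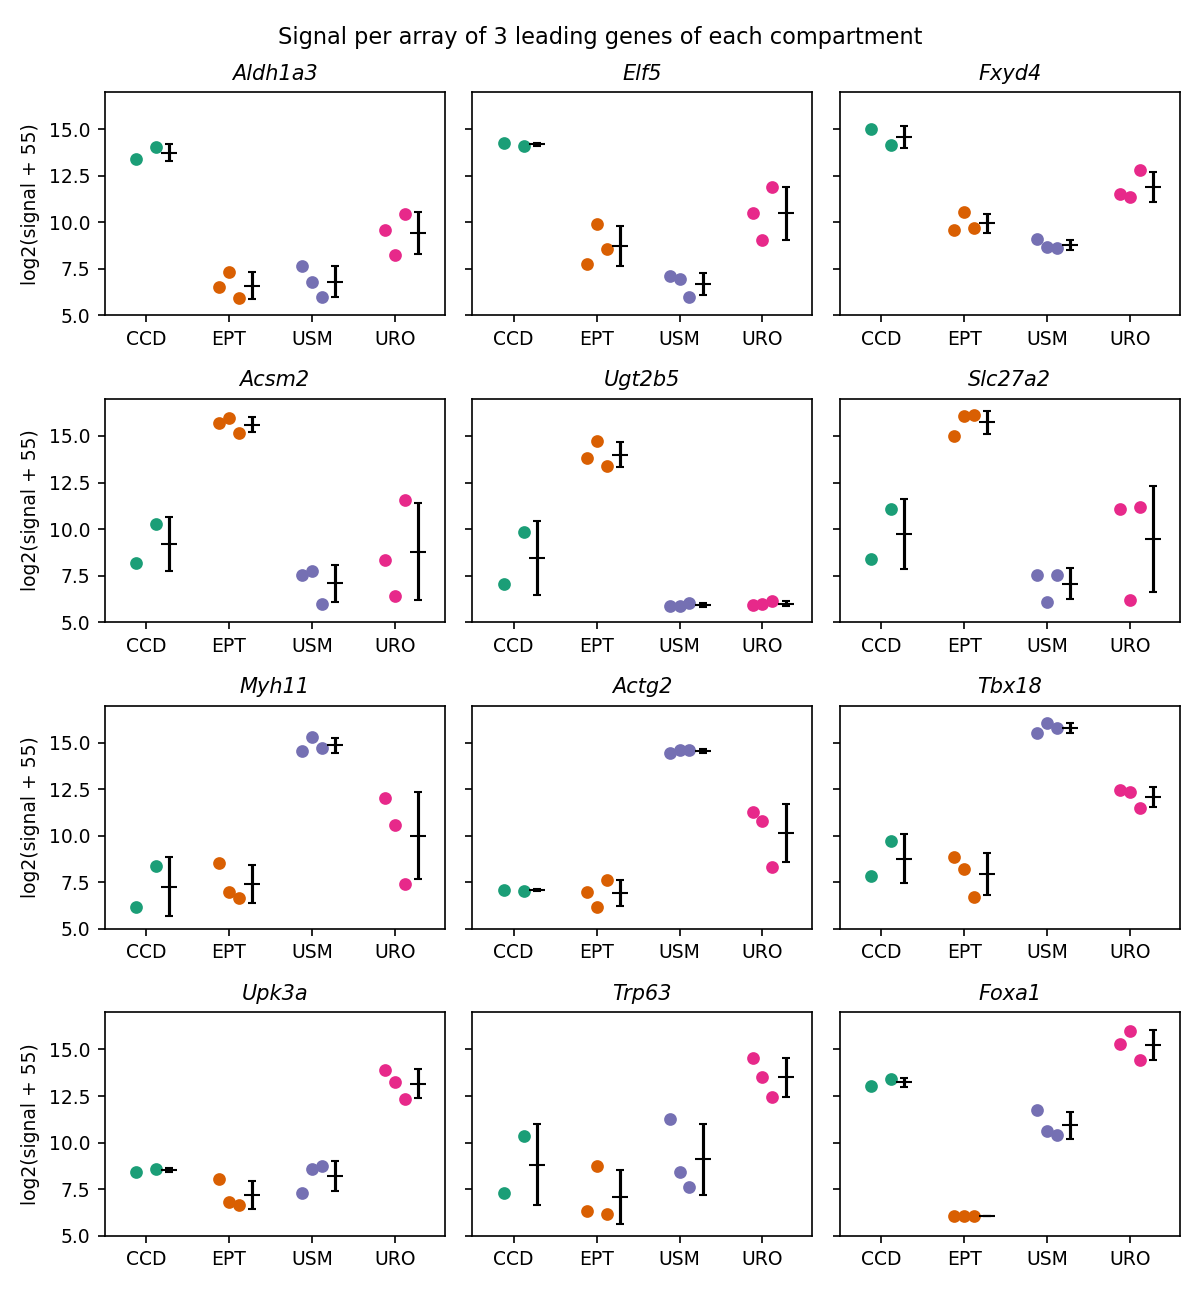
Log2(signal + 55) of 3 leading genes of each compartment in every array, as 1 coloured point per array with the mean and SD of each compartment (n = 2, 3, 3 and 3) as a black mark beside the points. In each panel the arrays of the gene's own compartment lie above all other arrays, and Foxa1 is also high in collecting duct (mean 13.24) and at 6.06 in proximal tubule.

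Ureteral smooth muscle carried the contractile genes. Myh11, the smooth muscle myosin heavy chain, was higher than the mean of the other compartments by a log2 fold change of 6.64 ± 0.79 (SE, n = 3 against 8), and the enteric and cardiac actins Actg2 and Actc1 by 6.51 ± 0.53 and 6.40 ± 0.53. Myocd, the coactivator that drives smooth muscle genes, was higher by 5.97 ± 0.74, and Tbx18, a transcription factor of ureteral mesenchyme, by 6.18 ± 0.49. Epithelial genes were lower, Dcdc2a by the widest margin of those named (-8.09 ± 0.63), followed by Slc47a1 (-6.11 ± 0.51) and the polycystic kidney disease gene Pkhd1 (-5.93 ± 0.51). Other leading genes were Car3 5.78, Nptx2 5.56, Hhip 5.52, Tnnt2 5.51, Myl9 5.41, Tagln 5.40 and Lum 5.38 on the higher side and Pou3f3 -5.67, Map3k21 -5.66 and Hook1 -5.57 on the lower side, with limma adjusted p from 1.98e-06 to 0.00012.

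Smooth muscle contractile genes had 21 of 26 measured members higher, 0 lower and 5 not called. Contractile genes gave 22 higher and 0 lower adjusted over the list alone, the calponin Cnn1 4.64 among them, with a list median of 3.61. Camera adjusted p was 2.07e-24 for this list, and 0.023 with an estimated correlation. The 3' control signal of beta-actin was 67721 to 75054 in the 3 muscle arrays and 7167 to 56583 in the other arrays. Its 3' to 5' ratio, a measure of RNA integrity, was 7.71, 8.16 and 5.07 in muscle replicates 1, 2 and 3. Ureteral mesenchyme and hedgehog targets had 12 of 15 measured members higher, 1 lower and 2 not called. Ureteral mesenchyme genes gave 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.31e-11), with the hedgehog-binding protein Hhip, Tshz3 3.13 and Foxf1 4.70 higher and Tbx2 -1.63 lower. The extracellular matrix list had 20 of 27 measured members higher, 0 lower and 7 not called. Extracellular matrix genes gave 21 higher and 0 lower adjusted over the list alone (camera adjusted p = 7.89e-17, and adjusted p = 0.111 with an estimated correlation), among them the proteoglycans Dcn 4.72 and Lum, Col6a3 3.81 and Col12a1 3.13. The renal interstitium list had 6 of 13 measured members higher, 1 lower and 6 not called. Interstitial genes gave 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000213, and adjusted p = 0.326 with an estimated correlation), with Tcf21 3.16, Vim 2.57 and Zeb2 2.51 higher and Wnt4 -3.55 lower. Cell cycle genes had 2 of 23 measured members higher, 0 lower and 21 not called. Cell cycle genes gave 0 higher and 0 lower adjusted over the list alone, with a list median of 0.65 (camera adjusted p = 3.64e-05, and adjusted p = 0.169 with an estimated correlation), the called members being Ccna2 1.25 and Cdk1 1.14. The endothelium list had 1 of 16 measured members higher, 0 lower and 15 not called. Endothelium genes gave 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0375, and adjusted p = 0.48 with an estimated correlation), with Cd34 1.86 called.

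General epithelial genes had 0 of 22 measured members higher, 21 lower and 1 not called. General epithelial genes gave 0 higher and 22 lower adjusted over the list alone, with a list median of -3.59 (camera adjusted p = 3.67e-23), among them E-cadherin (Cdh1 -4.74), Cldn7 -5.57 and Spint2 -4.71. Proximal tubule transporters had 1 of 31 measured members higher, 18 lower and 12 not called. These transporters gave 1 higher and 22 lower adjusted over the list alone (camera adjusted p = 5.11e-10, and adjusted p = 0.0523 with an estimated correlation). Brush border and endocytosis genes had 0 of 19 measured members higher, 14 lower and 5 not called. Brush border genes gave 0 higher and 15 lower adjusted over the list alone (camera adjusted p = 7.97e-11, and adjusted p = 0.0523 with an estimated correlation). Proximal tubule metabolism genes had 0 of 30 measured members higher, 17 lower and 13 not called. Metabolism genes gave 0 higher and 19 lower adjusted over the list alone (camera adjusted p = 6.27e-09, and adjusted p = 0.0523 with an estimated correlation). Examples from these lists were Slc7a9 -4.27, Slc9a3r1 -4.17 and Gsta2 -4.54, and the water channel Aqp1 1.81 was the transporter list's higher member. The principal cell list had 0 of 13 measured members higher, 8 lower and 5 not called. Principal cell genes gave 0 higher and 10 lower adjusted over the list alone (camera adjusted p = 1.20e-06, and adjusted p = 0.0523 with an estimated correlation), with Tfcp2l1 -4.82 and Elf5 -4.44. The ureteric bud and duct list had 1 of 15 measured members higher, 8 lower and 6 not called. Ureteric bud genes gave 1 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.000168, and adjusted p = 0.123 with an estimated correlation), with Emx2 -4.24 lower and Gata2 1.94 higher. Urothelial differentiation genes had 0 of 21 measured members higher, 7 lower and 14 not called. Urothelial genes gave 0 higher and 9 lower adjusted over the list alone (camera adjusted p = 4.03e-05, and adjusted p = 0.22 with an estimated correlation), with Ehf -3.92 and Shh -4.76. Desmosome and stratified epithelium genes had 0 of 17 measured members higher, 10 lower and 7 not called. Desmosome genes gave 0 higher and 11 lower adjusted over the list alone (camera adjusted p = 8.07e-06, and adjusted p = 0.0869 with an estimated correlation), with Dsp -4.55 and Pkp2 -4.90. The loop of Henle list had 0 of 12 measured members higher, 4 lower and 8 not called. Loop of Henle genes gave 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.00354, and adjusted p = 0.147 with an estimated correlation), Pou3f3 among the lower. The nephron progenitor list had 0 of 12 measured members higher, 4 lower and 8 not called. Nephron progenitor genes gave 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0445, and adjusted p = 0.451 with an estimated correlation), with Sall1 -3.85 and Eya1 -3.23.

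The other 12 lists were not called in smooth muscle (camera adjusted p from 0.0972 to 0.931). Across all genes, 2065 of 13614 were called by limma, 823 higher and 1242 lower, and 1201 of them did not overlap between compartments (10.3% of genes tested, against 1.21% by chance). With label batch as a block 951 genes were called (406 higher, 545 lower), 916 of them also called without it. All 2065 kept their sign with the block, on the arrays that chose them, their median log2 size going from 1.97 to 1.91 and the median SE of all genes from 0.390 to 0.474. Over the alternatives, of the 94 called genes that the rule named, 18 lost the call with the block, 2 to 12 without single arrays and 0 to 12 under the other alternatives. Without the 2 arrays of label batch 2, a choice made after the data were seen, the count was 1350.

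The leading genes of urothelium included uroplakins, the membrane proteins of the urinary tract lining. Upk3a was higher than the mean of the other compartments by a log2 fold change of 5.21 ± 0.45 (SE, n = 3 against 8) and Upk1b by 4.79 ± 0.59. The basal cell transcription factor Trp63 was higher by 5.18 ± 0.84, Foxa1 by 5.18 ± 0.39 and the keratin Krt19 by 4.84 ± 0.40. The sphingolipid genes Sptssb, a subunit of serine palmitoyltransferase, and Cers3, a ceramide synthase, were higher by 5.42 ± 0.47 and 4.57 ± 0.44. Itga5, an integrin subunit, was lower (-2.53 ± 0.28), as was the acetyl-CoA synthetase Acss1 (-2.67 ± 0.40). The other leading genes were S100a6 4.6, Fxyd3 4.53, Tspan8 4.32, Fos 4.32 and Anxa8 4.26 on the higher side and Tspan18 -2.61, Sgip1 -2.48, Rgmb -2.40 and Syt2 -2.38 on the lower side, with limma adjusted p from 6.4e-05 to 0.0405.

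Urothelial differentiation genes had 14 of 21 measured members higher, 0 lower and 7 not called. Urothelial genes gave 17 higher and 0 lower adjusted over the list alone, with a list median of 2.69. By camera the list's adjusted p was 1.67e-24, and 0.0382 with an estimated correlation. General epithelial genes had 13 of 22 measured members higher, 0 lower and 9 not called. General epithelial genes gave 18 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.68e-20), with Esrp1 3.10, a splicing regulator, and the keratin Krt18 3.27. The desmosome and stratified epithelium list had 7 of 17 measured members higher, 0 lower and 10 not called. Desmosome genes gave 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.70e-09), among them Perp 3.48, Lamb3 3.10, a laminin chain, Dsc2 3.14 and Trim29 2.11. BMP targets had 2 of 10 measured members higher, 0 lower and 8 not called. BMP targets gave 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0126, and adjusted p = 0.166 with an estimated correlation), the called members being Msx2 3.71 and Id1 1.69. Immediate early and stress genes had 1 of 14 measured members higher, 0 lower and 13 not called. Immediate early genes gave 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0239, and adjusted p = 0.115 with an estimated correlation), Fos being the member called. Cell cycle genes had 0 of 23 measured members higher, 0 lower and 23 not called. Cell cycle genes gave 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0274, and adjusted p = 0.444 with an estimated correlation).

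Proximal tubule transporters were lower, with 0 of 31 measured members higher, 6 lower and 25 not called. These transporters gave 0 higher and 12 lower adjusted over the list alone (camera adjusted p = 9.40e-12), including Slc17a1 -2.91 and Slc3a1 -2.16. Brush border and endocytosis genes had 0 of 19 measured members higher, 1 lower and 18 not called. Brush border genes gave 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00389, and adjusted p = 0.326 with an estimated correlation), with Dpep1 -2.35 called in the full test. Proximal tubule metabolism genes had 1 of 30 measured members higher, 4 lower and 25 not called. Metabolism genes gave 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 3.18e-06, and adjusted p = 0.0971 with an estimated correlation), with Spp2 -2.20 and Pck1 -1.61 lower and Ttr 4.04, the thyroid hormone carrier transthyretin, higher. The intercalated cell list had 0 of 8 measured members higher, 1 lower and 7 not called. Intercalated cell genes gave 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0165, and adjusted p = 0.111 with an estimated correlation), with the anion exchanger Slc26a4 -2.01 called. Extracellular matrix genes had 0 of 27 measured members higher, 0 lower and 27 not called. Extracellular matrix genes gave 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0493, and adjusted p = 0.626 with an estimated correlation), and this list's direction turned without urothelium replicate 2 (extracellular matrix camera adjusted p = 0.414, and 0.000758 to 0.981 over the alternatives). The smooth muscle contractile list was not called (camera adjusted p = 0.109), with 1 of 26 measured members higher, 0 lower and 25 not called. Contractile genes gave 1 higher and 0 lower adjusted over the list alone, the small heat shock protein Hspb1 1.69 being the member called. Over 48 genes high in muscle and low in collecting duct and proximal tubule, the median level above those was 13.8%, 4.69% and 3.68% of the muscle level in urothelium replicates 1, 2 and 3.

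The remaining 16 lists were not called in urothelium (camera adjusted p from 0.0778 to 0.97). Limma called 322 of 13614 genes, 225 higher and 97 lower, and 149 of them did not overlap between compartments (2.93% of genes tested, against 1.21% by chance). With label batch as a block limma called 0 genes (920 at an unadjusted p under 0.05), while all 322 kept their sign on the arrays that chose them, their median log2 size was 2.11 both ways and the median SE of all genes went from 0.390 to 0.670, and of the 45 called genes that the rule named, 45 lost the call with the block, 2 to 18 without single arrays and 0 to 17 under the other alternatives. The count was 128, 98 and 201 without urothelium replicate 1, urothelium replicate 2 and collecting duct replicate 2, and 120 without the 2 arrays of label batch 2. The fit with the block linked urothelium to collecting duct and proximal tubule only through muscle replicate 2, the muscle array of label batch 4. The sizes from that fit therefore rest partly on that array.

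**Figure D3:**
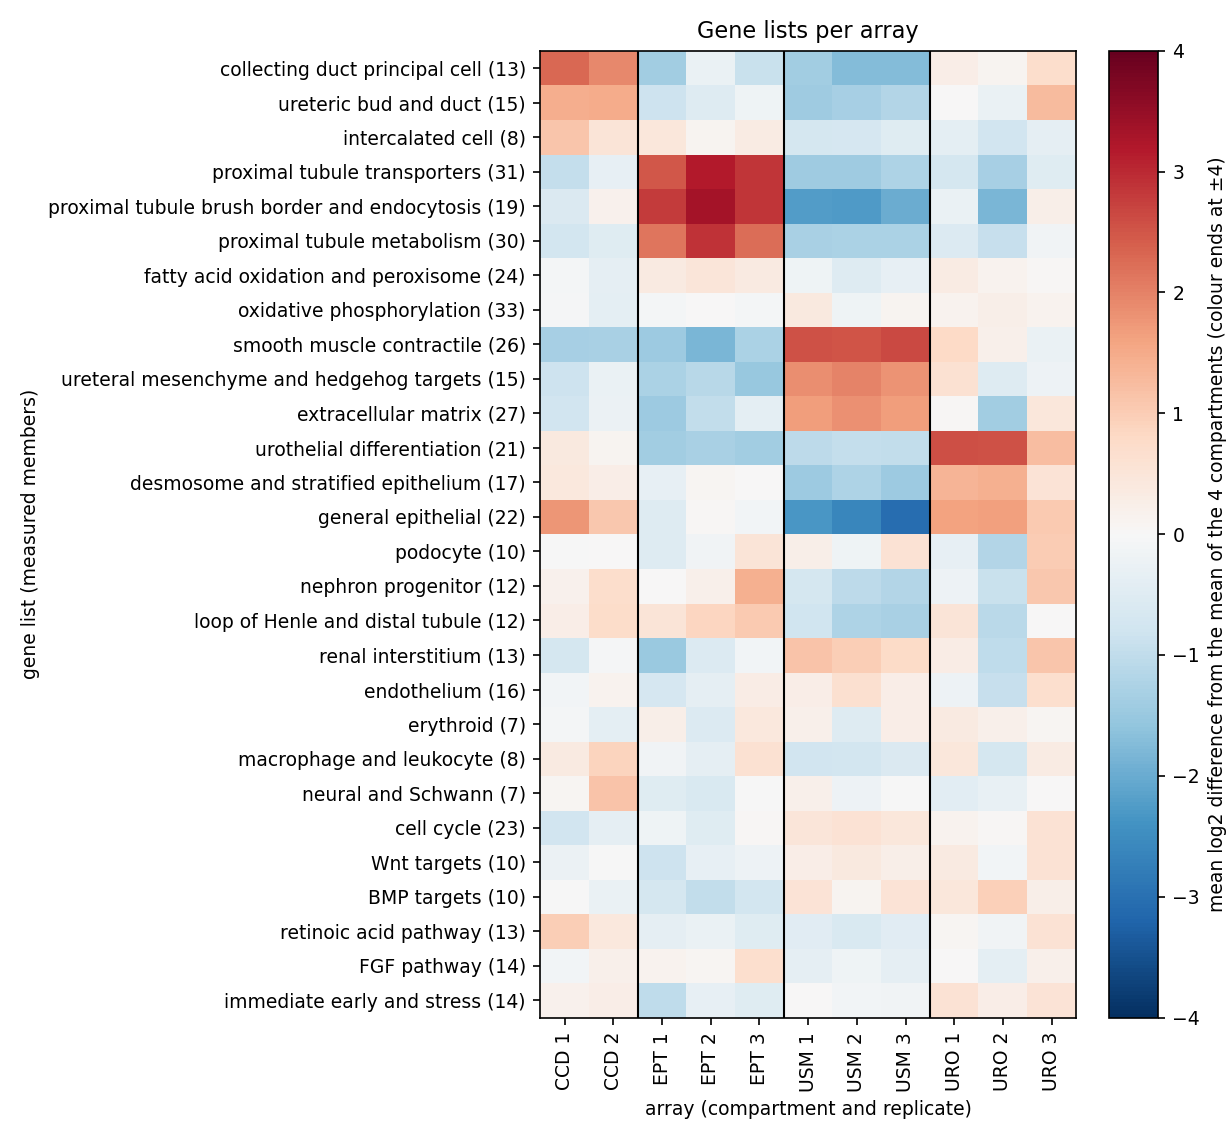
Mean log2 difference of each gene list (rows, measured members in brackets) from the mean of the 4 compartments in each array (columns), from blue (lower) through white (0) to red (higher), with black lines between compartments. The proximal tubule, smooth muscle and urothelial lists are red in their own arrays, and the urothelial differentiation list is paler in urothelium replicate 3 (1.23) than in replicates 1 and 2 (2.58 and 2.55).

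Each of these 4 comparisons sets 1 compartment against the mean of the other 3, so a list that is high in 1 compartment lowers its value in the others. The lists called with an estimated correlation were the principal cell, ureteric bud, smooth muscle and general epithelial lists in collecting duct, the 3 proximal tubule lists and the smooth muscle list in proximal tubule, the smooth muscle, ureteral mesenchyme and general epithelial lists in muscle, and the urothelial, desmosome, general epithelial and proximal tubule transporter lists in urothelium. With that correlation their camera adjusted p ran only from 0.023 to 0.042, far above the values at the preset correlation. Over the 4 comparisons 7 lists were never called: podocyte, erythroid, macrophage and leukocyte, neural and Schwann, FGF pathway, Wnt target, and fatty acid oxidation and peroxisome genes. The median and the direction of the test differed in sign for lists that were not called: in collecting duct the urothelial (median -0.13), podocyte (0.11) and Wnt target (0.21) lists, in proximal tubule the general epithelial (0.09) and leukocyte (0.19) lists, in muscle the immediate early list (0.0118), and in urothelium the principal cell (-0.23), leukocyte (-0.0976) and FGF pathway (0.18) lists. The median and the mean also differed in sign for the erythroid list in proximal tubule (-0.32 and 0.0611) and in muscle (0.21 and -0.0154).

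Urothelium and cortical collecting duct, the pair with the closest profiles, differed in 35 genes called by limma, with 1637 at an unadjusted p under 0.05. Sptssb was higher in urothelium by a log2 fold change of 5.50 ± 0.63 (SE, n = 3 against 2), Upk3a by 4.67 ± 0.60, the immediate early gene Fos by 4.65 ± 0.71, the small GTPase Arl14 by 4.61 ± 0.54, S100a6 by 4.58 ± 0.54 and Upk1b by 4.38 ± 0.80. Aldh1a3 was lower in urothelium (-4.33 ± 0.67), as was Tenm1 (-4.26 ± 0.76), followed by Afm -3.47, the nuclear RNA Neat1 -3.29, Opcml -3.25 and Rasgrf2 -3.20. Of the 35 genes 22 were higher and 13 lower, with adjusted p from 0.00433 to 0.0471 for those named, and 35 of the 35 did not overlap between the arrays (27.8% of genes tested, against 20% by chance). No label batch holds both compartments, limma called 0 genes with label batch as a block (630 at an unadjusted p under 0.05), and the median log2 size of the 35 went from 3.29 to 3.19 as the median SE of all genes went from 0.523 to 0.871. Limma called 0 genes without collecting duct replicate 1 or without replicate 2 (1407 and 1290 at an unadjusted p under 0.05), 7 without urothelium replicate 1, 6 without replicate 2 and 147 without replicate 3. With the lower and the higher pseudocount 22 and 122 were called, and of the 12 called genes that the rule named, 12 lost the call with the block, 0 to 12 without single arrays and 0 to 8 under the other alternatives. The ureteric bud list lay 1.27 above the mean of the 4 compartments in urothelium replicate 3, at 0.00 and -0.26 in replicates 1 and 2, and at 1.46 and 1.5 in the collecting duct arrays.

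Urothelium and the muscle around it differed in epithelial and mesenchymal genes. Dcdc2a was higher in urothelium by 6.18 ± 0.76 (SE, n = 3 against 3), the claudin Cldn7 by 6.11 ± 0.51, Slc47a1 by 5.94 ± 0.62, Tspan8 by 5.90 ± 0.74, the sodium channel subunit Scnn1g by 5.78 ± 0.64 and Shh by 5.78 ± 0.83. Lower in urothelium were Nptx2 (-5.23 ± 0.63), Hhip (-5.16 ± 0.69), Myh11 (-4.85 ± 0.94), Scara5 -4.57, Entpd1 -4.48 and the GDNF family receptor Gfra2 -4.43. The general epithelial list had a median difference of 4.77 in label batch 1 and 4.09 in label batch 2, the smooth muscle contractile list of -2.58 and -1.86, and the urothelial differentiation list of 2.92 and 3.29. Limma called 1084 genes, 685 higher and 399 lower, with adjusted p from 2.93e-05 to 0.00583 for those named. All 1084 had the same sign within each of the 2 label batches that hold both compartments, on the arrays that chose them, and 719 genes were called with label batch as a block, where Myh11 was not (limma adjusted p = 0.0505, and 0.000239 to 0.0505 over the alternatives). Without probe sets of the x, s and a types Gfra2 was read from another probe set, at -0.56 ± 0.49 (limma adjusted p = 0.636, and 6.06e-06 to 0.636 over the alternatives). Without the 2 arrays of label batch 2 the count was 657.

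Cortical collecting duct and early proximal tubule differed in duct and tubule genes. Cldn8 was higher in collecting duct by 7.41 ± 0.72 (SE, n = 2 against 3), Foxa1 by 7.18 ± 0.53, Aldh1a3 by 7.14 ± 0.67, Shh by 6.54 ± 0.93, Tspan8 by 6.14 ± 0.83 and the tyrosine kinase Frk by 5.87 ± 0.66. Lower in collecting duct were Slc22a22 (-6.49 ± 0.50), Cyp2d26 (-6.41 ± 0.94), Acsm2 (-6.39 ± 1.12), Slc47a1 -6.27, Susd3 -6.24 and Slc27a2 -6.00. The principal cell list had a median difference of 2.40 in label batch 3 and 3.93 in label batch 4, and the proximal tubule transporter list of -3.60 and -3.58. Limma called 795 genes, 298 higher and 497 lower, with adjusted p from 3.85e-05 to 0.00994 for those named. All 795 had the same sign within each of the 2 label batches that hold both compartments, on the arrays that chose them, and 627 genes were called with label batch as a block. The count was 359, 364 and 482 without collecting duct replicate 1, collecting duct replicate 2 and proximal tubule replicate 2, and the direction of Susd3 turned to 0.11 ± 0.58 with the lower pseudocount. With that pseudocount Susd3 was read from another probe set. Without collecting duct replicate 1 Acsm2 and Slc27a2 were not called, at -5.36 ± 1.41 and -4.68 ± 1.51, nor was Slc27a2 with the lower pseudocount (-6.11 ± 1.62).

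For the other 3 pairs the rule for named genes chose none. Proximal tubule and smooth muscle differed in the most genes, 2771 (1674 higher and 1097 lower in proximal tubule), with 2769 of the same sign in label batch 4, on arrays that helped to choose them, and 710 called with label batch as a block. Collecting duct and smooth muscle differed in 1126 genes (669 higher and 457 lower in collecting duct), 1126 of the same sign in label batch 4, again on arrays that helped to choose them, with 302 called under the block, 520 without collecting duct replicate 1 and 673 without replicate 2. Urothelium and proximal tubule differed in 1560 genes (683 higher and 877 lower in urothelium), share no label batch, and had 24 called under the block, 899 without proximal tubule replicate 2, 1012 without urothelium replicate 1 and 1012 without the 2 arrays of label batch 2.

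**Figure D4:**
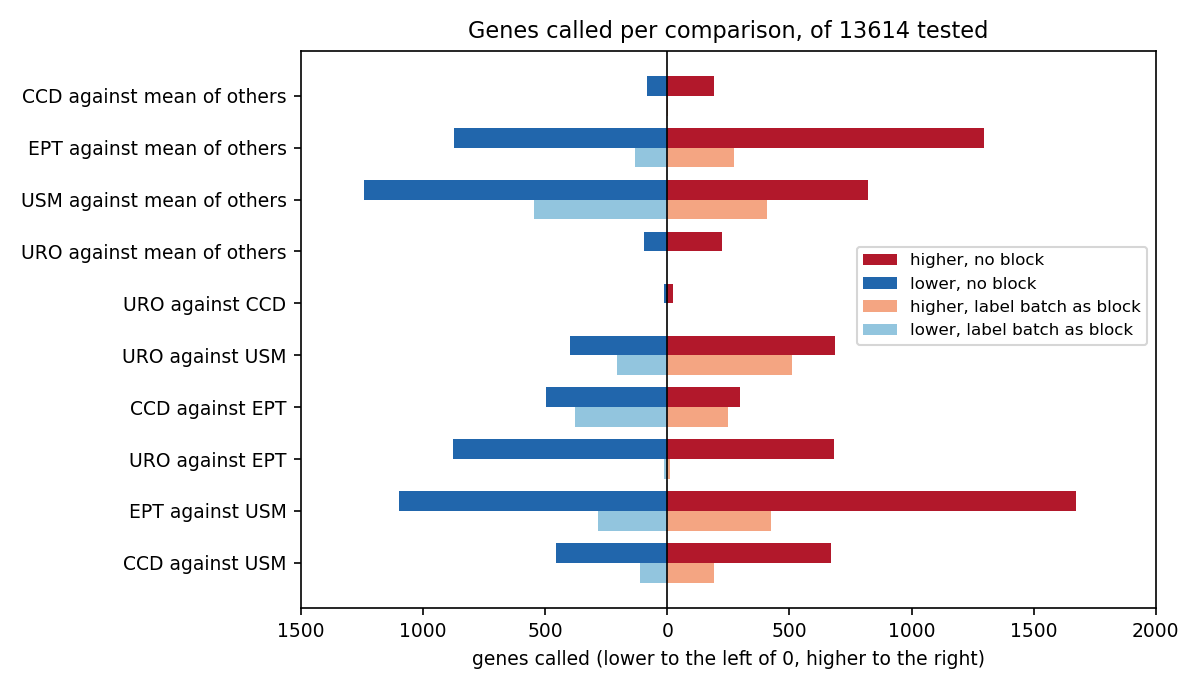
Genes called by limma per comparison, as bars to the right of 0 for genes higher and to the left for genes lower in the compartment named at the start of each label, dark without a block and pale with label batch as a block. Without a block, the higher and lower bars together are longest for proximal tubule against muscle (1674 higher, 1097 lower) and shortest for urothelium against collecting duct (22 higher, 13 lower).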

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

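The alternatives without the 2 arrays of label batch 2 and without genes on chromosomes X and Y were chosen after the results were seen. Over all alternatives, named genes kept direction and side of the threshold in 10986 comparisons with the reported value, lost the call in 739, gained one in 121, moved in 29 and reversed in 3. For the lists these counts were 2314, 88, 64, 88 and 2. The counts of kept values include named genes and lists called neither in the reported fit nor in the alternative. They also pool comparisons that differ widely. With label batch as a fixed block, 49 of 49 called named genes in collecting duct and 45 of 45 in urothelium lost the call. So did 12 of 12 for urothelium against collecting duct. No paired analysis was possible because the replicate numbers were given in accession order and pair nothing, and label batch, which does hold arrays of several compartments, was fitted as a block in its place. Label batch as a random block had an estimated correlation of 0.0268, and camera takes no random block, so no list has a value there.

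With label batch as a fixed block, counts went from 278 to 3 in collecting duct, 2169 to 406 in proximal tubule, 2065 to 951 in muscle, 322 to 0 in urothelium by limma (920 at an unadjusted p under 0.05), 35 to 0 for urothelium against collecting duct by limma (630 at an unadjusted p under 0.05), 1084 to 719 for urothelium against muscle, 1560 to 24 for urothelium against proximal tubule, 2771 to 710 for proximal tubule against muscle and 1126 to 302 for collecting duct against muscle. The block leaves 4 residual degrees of freedom in place of 7, and median SEs went from 0.390 to 0.670 in urothelium and from 0.523 to 0.871 for urothelium against collecting duct. Under the block, urothelium is compared with collecting duct and proximal tubule only by way of muscle replicate 2, the muscle array of label batch 4. Of the called genes 99.5% to 100% kept their sign, on the arrays that chose them, so the sign is not independent support.

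With the 5th percentile pseudocount the counts were 173 in collecting duct, 202 in urothelium and 22 for urothelium against collecting duct, and with the 40th percentile 421 in collecting duct and 122 for that pair. That pair also had 58 with the filter at the 75th percentile and 67 with trend and robust options, and the cause was not tested for these. With an estimated correlation 4, 4, 3 and 4 lists were called in collecting duct, proximal tubule, muscle and urothelium, where the preset gave 12, 13, 16 and 11. Without the 2 arrays of label batch 2, which leaves fewer samples, the counts were 1350 in muscle, 120 in urothelium, 7 for urothelium against collecting duct, 657 for urothelium against muscle and 1012 for urothelium against proximal tubule.

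Leaving out each array in turn gave 10 to 306 genes in collecting duct, 1232 to 2227 in proximal tubule, 1381 to 2079 in muscle and 98 to 398 in urothelium. For the pairs it gave 0 to 147 for urothelium against collecting duct (0 by limma without either collecting duct array, with 1407 and 1290 at an unadjusted p under 0.05), 740 to 1084 for urothelium against muscle, 359 to 821 for collecting duct against proximal tubule, 899 to 1562 for urothelium against proximal tubule, 1912 to 2870 for proximal tubule against muscle and 520 to 1252 for collecting duct against muscle. Lists called ran from 11 to 16, 11 to 15, 15 to 16 and 9 to 13 in the 4 compartments. Without a collecting duct array 1 is left, which is assumed to vary like the other groups. The lowest counts were without collecting duct replicate 1 (10), proximal tubule replicate 2 (1232), muscle replicate 1 (1381) and urothelium replicate 2 (98).

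Reversed values were Susd3 in collecting duct against proximal tubule (0.1092 with the 5th percentile pseudocount), Tpm2 in collecting duct (0.0703) and Gadd45b in proximal tubule (0.235). Tpm2 and Gadd45b were read from another probe set without the x, s and a types. Susd3 was read from another probe set with the lower pseudocount. Within 1 probe set a pseudocount keeps the order of the arrays, and these groups did not overlap. The oxidative phosphorylation list in collecting duct reversed under the fixed block (camera adjusted p = 0.999, range 0.00938 to 0.999), and the extracellular matrix list in urothelium without replicate 2 (camera adjusted p = 0.414, range 0.000758 to 0.981). The cause was not tested. Signal near the background limits dim genes, whose folds depend on the pseudocount.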

Other observations

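The tests of sex-linked transcripts, of muscle transcripts in single urothelium arrays and of Ptprc were chosen after the results were seen, and the relabelling counts before. Some genes of the signalling and progenitor lists that the rule named are given here. In muscle the FGF pathway list was not called (camera adjusted p = 0.259), with 1 of 14 members higher, Fgf7 (3.42 ± 0.43, SE, n = 3 against 8), and 1 lower, Fgf9 (-3.56 ± 0.40). The Wnt target list was not called in muscle either (camera adjusted p = 0.132), with Apcdd1 and Nkd1 higher (2.69 ± 0.40 and 2.36 ± 0.37), Dkk1 lower (-2.95 ± 0.47) and 7 members not called, nor in proximal tubule (camera adjusted p = 0.0707), with 4 of 10 members lower and 0 higher. The neural and Schwann list was also not called in muscle (camera adjusted p = 0.55), with Ednrb, an endothelin receptor, higher (2.97 ± 0.54), Erbb3, a neuregulin receptor, lower (-5.03 ± 0.50) and 5 members not called. Shh had a mean log2 signal of 15.16 ± 0.33 in collecting duct (SD, n = 2), 13.41 ± 0.87 in urothelium, 8.62 ± 1.66 in proximal tubule and 7.64 ± 1.55 in muscle (n = 3 each), and the hedgehog target Hhip was higher in muscle (5.52 ± 0.57). Among the genes given here, calls lost with label batch as a block were Dll1 and Sall1, the 2 of 12 nephron progenitor genes higher in proximal tubule (3.23 ± 0.54 and 2.98 ± 0.59, and 2.86 ± 0.87 and 2.84 ± 1.03 with the block), and Wnt4, higher in urothelium (2.99 ± 0.52, and 3.87 ± 0.93 with the block). Wnt4 was also not called without urothelium replicate 2 (2.95 ± 0.62).

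Some genes were chosen after their values were seen. Umod, the uromodulin gene of the thick ascending limb, had a log2 signal of 11.49 in urothelium replicate 1 and 11.11 in muscle replicate 1, the 2 arrays of label batch 2. Slc12a1, a sodium transporter of the same segment, was at 13.60 in urothelium replicate 1 and 13.28 in collecting duct replicate 2. Fos was at 9.80 to 12.64 in urothelium, while Egr1 was at 8.29 to 12.59 and Jun at 10.86 to 11.74 there. In urothelium replicate 3 the nephron progenitor and podocyte lists lay 1.07 and 1.03 above the mean of the 4 compartments, and in replicate 2 they lay at -0.88 and -1.18. Over the proximal tubule arrays the nephron progenitor list, which holds Dll1 and Sall1, ran from 0.02 to 1.41 on that measure. The differences between label batches 3 and 4 in collecting duct and in proximal tubule had a Pearson r of 0.167 across genes, and those between batches 1 and 2 in urothelium and in muscle 0.196, genes not being independent replicates.

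Relabelling the 11 arrays into groups of the same sizes tested the counts, with 100 relabellings that include the real one. As many called genes came from 1 relabelling in collecting duct (278, highest other 53), 1 in proximal tubule (2169, highest other 1092), 1 in muscle (2065, highest other 1123) and 3 in urothelium (322, highest other 1252). This argues against the case in which no compartment differs from any other. Most relabellings mix compartments within groups, which widens the shared estimate of spread. The test therefore cannot tell whether the calls of any single compartment exceed chance. The relabellings do not keep label batches together, so they leave open how far batch adds to a count, which with label batch as a block was 3 in collecting duct, 406 in proximal tubule, 951 in muscle and 0 in urothelium (920 at an unadjusted p under 0.05 by limma). The 2 others in urothelium, with 1252 and 1000 genes, put the urothelium label on the 3 muscle arrays, which points to the structure of the samples. As many lists came from 29 relabellings in collecting duct (12, highest other 17), 17 in proximal tubule (13, highest other 17), 2 in muscle (16, highest other 16) and 41 in urothelium (11, highest other 16). With the same limit, chance assignment of all 11 arrays is argued against for the number of lists in muscle and not in the others. For pairs of 3 arrays against 3, the 10 splits are too few for a share under 0.05: 1 split gave as many genes for urothelium against muscle (1084, highest other 0), 1 for urothelium against proximal tubule (1560, highest other 1) and 1 for proximal tubule against muscle (2771, highest other 0).

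Xist and the Y-linked Eif2s3y set arrays of the same compartment apart. Xist was under 10 on the log2 scale in 5 arrays, all of them with Eif2s3y at 10.5 or more, and over 10 in 6, of which 4 also had Eif2s3y over 10. The other 2 had Eif2s3y at 9.89, just under that cut, and at 6.78. A single failing probe set is argued against, since both bright Xist probe sets fell on the same side of 10 in 11 arrays, and sex-linked genes making up the calls are argued against by their 3.46% of called proximal tubule genes beside 3.26% of tested genes. Pools of fetuses differing in sex stay open as a candidate explanation, with 0 arrays under 10 for both transcripts, and the labels give the sex as unknown.

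Smooth muscle transcripts were present in the urothelium arrays, over 48 genes high in muscle and low in collecting duct and proximal tubule. In urothelium replicate 1 their median share of the muscle level was 13.8%, with 91.7% of genes within 4-fold of it, as carry-over of ureteral muscle into the capture may give. The share of the listed contractile genes there was 1.43 times that of the others, which argues against own expression of those genes alone. All 48 genes were chosen as high in muscle. A wider set of muscle genes expressed by the urothelium itself could raise both shares, so the ratio cannot exclude it. In urothelium replicate 2, with a median share of 4.69%, 58.3% within 4-fold and a ratio of 2.30, carry-over and own expression cannot be told apart, because both values fell between the bounds set for and against each. Replicate 3 had a median share of 3.68%, 75% of genes within 4-fold and a ratio of 0.618, the other way from replicate 2.

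Ptprc, the leukocyte surface gene CD45, was higher in collecting duct by a log2 fold change of 4.2 ± 1.00 (SE, n = 2 against 9, limma adjusted p = 0.0493, and up to 0.64 over the alternatives), and its log2 signal was also 10.82 in urothelium replicate 3 and 9.63 in proximal tubule replicate 3. Leukocytes that carry the list's myeloid genes as a set are argued against, since the other 7 members had a median of 0.0866, the lowest being Csf1r at -0.61. Mrc1 went with Ptprc (1.89 ± 0.495, limma adjusted p = 0.0735). Its log2 signal was 10.31 and 10.85 in collecting duct and at most 9.55 in the other arrays. The list gave 2 higher and 0 lower adjusted over the list alone, so leukocytes that carry few of these genes stay open. With label batch as a block Ptprc was at 3.09 ± 1.42 and the list's median went from 0.16 to 0.80, and leukocytes without myeloid genes were not tested. A signal of 1 probe set stays a candidate explanation that cannot be told apart from expression of the gene, because the second Ptprc probe set reached at most 8.08 in any array.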
